A study of Mus musculus with 8 samples.

How the data were processed

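RNA sequencing was done on 8 libraries of mouse embryonic stem cells, 2 for each of 4 conditions: wild-type (WT) cells of the V6.5 line, Dgcr8 knockout (KO) cells, Dgcr8 KO cells transfected with a miR-294 mimic, and Dgcr8 KO cells transfected with siRNAs against Mbnl1 and Mbnl2 (siMbnl1/2). The cells grew in serum with LIF on gelatin or on irradiated fibroblast feeders, and the labels do not say which was used for which sample. Mimics and siRNAs were given at 50 nM, 16 hours after plating, and the WT and Dgcr8 KO columns are mock transfections. All samples are labelled as V6.5, but the column names are V65-mock for WT and ES1-mock for Dgcr8 KO, so a shared parental line is not established, and Dgcr8 KO minus WT also holds any difference between lines. RNA was extracted with Trizol and the libraries were made by a strand-keeping dUTP protocol. The sample labels call the material polyA RNA and the series design calls it total RNA.

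The deposited table gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene and library for 49641 gene entries. The submitters' processing notes name STAR 2.5.0, Cufflinks 2.2.1 and the genome build mm10, and reads were not reprocessed here. FPKM is relative to each library's total, so a gain in abundant transcripts lowers the values of all others, and short genes have inflated values. Read counts cannot be recovered from FPKM, so the depth is unknown and no counting interval can be given. The FPKM of a library summed to between 473746 and 571508, and the 10 most abundant genes held 6.67% to 8.49% of it. The release of the gene annotation is not stated. Of the entries, 43792 carry the same identifier version as GENCODE M21, and 99.9% of those lie at the same coordinates.

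Values were analysed as log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 8 libraries were tested, which left 12786, of which 42 are small RNA genes; 296 entries share a symbol with another entry. On this scale a fold change between low values is understated. Each gene was fitted with 4 group means by limma 3.58.1 (R 4.3.3, statmod 1.5.0, and the data.table package, version 1.17.8), with a moderated variance that follows a trend with abundance and is robust to outlying genes. All 8 libraries shared that fit, since 2 libraries per group give few degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and all tests were two-sided. The comparisons were Dgcr8 KO minus WT, miR-294 minus Dgcr8 KO, siMbnl1/2 minus Dgcr8 KO, and siMbnl1/2 minus miR-294. Labels do not say that a replicate number marks a shared day, so the replicate number was left out of the fit and used as a block only as an alternative. With 2 libraries per group no library could be tested as an outlier within its group, and other splits of the samples were not counted.

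The genes to name were fixed by a rule. It takes Dgcr8, Mbnl1, Mbnl2 and Mbnl3 in every comparison. It adds the 5 largest increases and 5 largest decreases of each comparison with Dgcr8 KO among called genes whose groups do not overlap (3 each for the difference between treatments), leaving out symbols of predicted genes (Gm and LOC), names ending in Rik, small RNA genes and pseudogenes. Entries named after RP23 clones were not among those left out. It adds the 2 most changed called members of each gene list, by the share of members called, until about 30 genes are named. The 28 gene lists cover the pluripotency network, primed epiblast, neuroectoderm, mesoderm, endoderm and trophoblast markers, two-cell-like markers, mouse embryonic fibroblast markers, published targets of the embryonic stem cell cycle (ESCC) microRNAs, the microRNA pathway, microRNA host transcripts, let-7 targets, splicing regulators, G1/S inhibitors, G1/S cyclins and E2F factors, glycolysis, the Myc family and partners, p53 targets, interferon-stimulated genes, epithelial and mesenchymal markers, DNA methylation enzymes, germline genes, Nodal, TGF-beta and BMP signalling, the Hippo pathway, actin cytoskeleton and adhesion, reference genes and mitochondrially encoded genes. Lists with at least 5 tested genes were tested against the other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over 27 lists, and again with a correlation estimated per list. limma's fry was run beside it. It asks whether a list's genes move on balance one way or, in its mixed form, in either direction, without comparing them with other genes. These choices were made before the data were examined.

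Agreement between comparisons was measured by the correlation and covariance of log2 fold changes across genes. The comparisons share the Dgcr8 KO libraries, which alone produces a positive correlation, so the values were set beside 100 simulated draws of unchanged groups with the same shared controls. A second simulation gave each group its own spread and was added after the first result was seen. For seed matches, each gene's longest annotated 3' UTR was searched for AGCACTT, the heptamer pairing with positions 2 to 8 of miR-294. The medians of genes with and without a match were compared by permuting genes within 10 bins of UTR length (100000 resamples, and 10000 for alternatives), and against 20 shuffled heptamers. The miR-294 sequence was taken from general knowledge of the microRNA. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for this search and the plots.

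Alternatives changed one choice at a time: a pseudocount of 0.1, no filter or a filter at a mean FPKM of 5, median-of-ratios scaling, quantile normalization, a replicate block, no small RNA genes, a variance prior without trend or robustness, only the libraries of the comparison, a 2-fold minimum, each library left out in turn, an octamer or the shortest UTR for the seed test, and 1 control library per comparison for the correlations. Weighting libraries by the spread of their group was added after the data were seen. A group left with 1 library is assumed to vary like the other groups. The procedure was tested on simulated data with 200 changed genes in 12786, over 10 data sets with the spreads of these groups. Of the calls, 4.84% were false for Dgcr8 KO minus WT, 6.25% for miR-294 minus Dgcr8 KO, 10.9% for siMbnl1/2 minus Dgcr8 KO and 5.73% for siMbnl1/2 minus miR-294. For siMbnl1/2 minus Dgcr8 KO, 43.1% of log2 changes of 0.5, 91.5% of changes of 1 and 97.3% of changes of 2 were recovered. In 1 simulated data set with the glycolysis genes shifted, that list was called and so was 1 other list, which the estimated correlation did not call. Lists share members, such as Gapdh and Pgk1 in glycolysis and reference genes, so the other call need not be an error. The simulated genes varied independently, so this cannot show which correlation is better. A simulated shift of -0.1 for genes with the heptamer came back as -0.10 beyond UTR length. Exon usage and splicing cannot be read from gene-level FPKM and were not analysed here.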

Results

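Gene expression was measured in 8 libraries of mouse embryonic stem cells, 2 per condition. V6.5 is an embryonic stem cell line of the mouse background 129/C57BL/6. Dgcr8 binds primary microRNA transcripts together with the nuclease Drosha, and cells without it make no canonical microRNAs. miR-294 belongs to the miR-290 family, which is abundant in mouse embryonic stem cells. Mbnl1 and Mbnl2 are muscleblind-like RNA-binding proteins that regulate alternative splicing. The study's title sets the microRNA family against these proteins, and the 4 conditions ask what the loss of microRNAs changed, what a single microRNA put back, and what siRNAs against Mbnl1 and Mbnl2 did in the same cells. The labels leave open whether WT and Dgcr8 KO share a parental line, so Dgcr8 KO minus WT also holds any difference between lines. Between 12386 and 12860 genes per library had an FPKM of at least 1, and the number of reads behind each value is unknown. The 2 libraries of a group correlated across genes at a Pearson r of 0.987 in WT, 0.984 with miR-294, 0.973 in Dgcr8 KO and 0.971 with siMbnl1/2. The median within-group SD on the log2 scale was 0.046 in WT and 0.049 with miR-294, against 0.102 in Dgcr8 KO and 0.121 with siMbnl1/2. Nothing states that replicates were separate cultures, so the p-values measure only the spread between these samples. Levels are mean FPKM ± SD (n = 2 libraries), and changes are differences of mean log2(FPKM + 1) ± SE with adjusted p-values from limma. Genes described as largest are so among those the naming rule admits, which leaves out predicted genes, small RNA genes, names ending in Rik and pseudogenes, some of which changed more.

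Dgcr8, the deleted gene (ENSMUSG00000022718.11; mm10 chromosome 16, 18253948 to 18289249, minus strand), was at 22.4 ± 0.662 FPKM in WT and 8.19 ± 0.432 in Dgcr8 KO, a fall by 1.35 ± 0.10 (adjusted p = 3.47e-05). It stayed at 7.04 ± 0.329 with miR-294 and 7.24 ± 0.927 with siMbnl1/2, and gene-level FPKM does not show which exons the remaining transcripts hold. Mbnl2 (ENSMUSG00000022139.16; chromosome 14, 120275669 to 120431697, plus strand) rose from 12.9 ± 0.0643 in WT to 26.6 ± 2.79 in Dgcr8 KO (0.99 ± 0.12, adjusted p = 3.61e-04). It fell to 13.8 ± 0.804 after miR-294 (-0.90 ± 0.12, adjusted p = 8.60e-04) and to 12.8 ± 2.23 after the siRNAs (-1.01 ± 0.12, adjusted p = 0.0191), a call lost without Dgcr8 KO replicate 2 (adjusted p = 0.121), without a filter, with libraries weighted by the spread of their group and with the libraries of the comparison alone, with an adjusted p of up to 0.137. Mbnl1 (ENSMUSG00000027763.13; chromosome 3, 60472830 to 60629750, plus strand) rose from 4.96 ± 0.228 in WT to 8.71 ± 1.00 in Dgcr8 KO and fell to 5.04 ± 0.172 after miR-294 (-0.68 ± 0.10, adjusted p = 0.00113). With siMbnl1/2 it was at 6.80 ± 0.0621, a change of -0.31 ± 0.10 that did not pass the test (adjusted p = 0.158). The paralog Mbnl3 (ENSMUSG00000036109.17; chromosome X, 51117269 to 51206532, minus strand) was low throughout, at 1.73 ± 0.16 in WT, 1.00 ± 0.207 in Dgcr8 KO, 0.707 ± 0.14 with miR-294 and 0.636 ± 0.0114 with siMbnl1/2. Its fall in Dgcr8 KO by 0.45 ± 0.13 (adjusted p = 0.0159) was lost without WT replicate 2 or without Dgcr8 KO replicate 1, with an adjusted p of up to 0.0981.

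**Figure D1:**
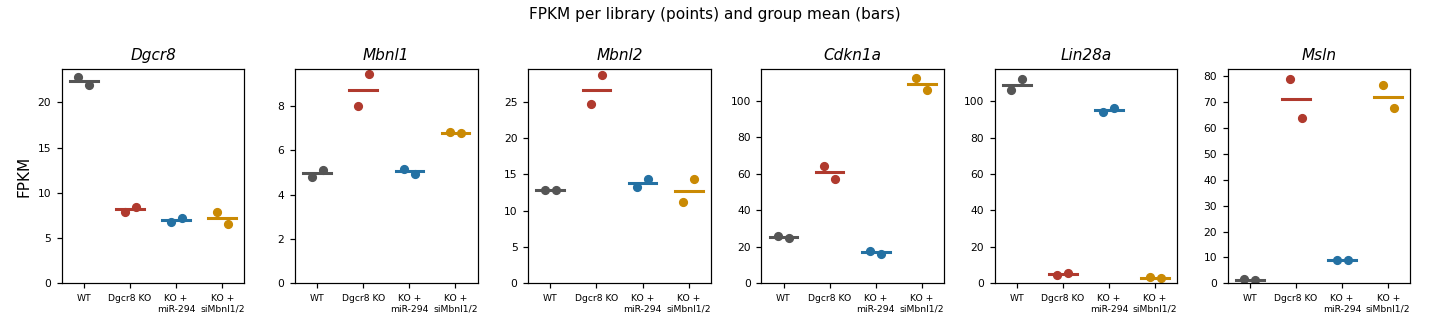
FPKM of Dgcr8, Mbnl1, Mbnl2, Cdkn1a, Lin28a and Msln in the 4 conditions, with 1 point per library and a bar at the mean of the 2 libraries. Mbnl2 is at 26.6 in Dgcr8 KO and between 12.8 and 13.8 in the other conditions, and Cdkn1a is lowest with miR-294 (16.9) and highest with siMbnl1/2 (109).

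In Dgcr8 KO cells Lin28a, Dab2 and Bmp4 fell, and Msln, Zbp1 and Ifitm1 rose. Lin28a, which blocks let-7 maturation (chromosome 4, 134003330 to 134018841), fell from 109 ± 4.33 FPKM in WT to 5.13 ± 0.558 in Dgcr8 KO (-4.17 ± 0.11, adjusted p = 1.50e-06). Dab2, an endocytic adaptor of primitive endoderm, fell by 4.20 ± 0.13, from 23.3 ± 0.585 to 0.322 ± 0.153. The signalling ligand Bmp4 fell from 27.3 ± 0.0689 to 0.774 ± 0.0478. Msln, the surface glycoprotein mesothelin, showed the largest increase of the genes admitted, from 1.49 ± 0.089 to 71.2 ± 10.6 (4.85 ± 0.11, adjusted p = 8.83e-07). Zbp1, a sensor of Z-form nucleic acids, rose from 0.116 ± 0.0343 to 16.6 ± 1.5, and Ifitm1, an interferon-induced membrane protein, from 60.0 ± 2.35 to 805 ± 171. The other large increases were Lrrc31 (3.67) and the aspartoacylase gene Aspa (3.62), and the other large decreases the trypsin inhibitor Spink1 (-4.14) and the carbonic anhydrase Car4 (-3.68).

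In all, 7641 of 12786 genes differed between Dgcr8 KO and WT, 3789 higher and 3852 lower, and 1565 of them by at least 2-fold (1066 higher, 499 lower). Myc (chromosome 15, 61985391 to 61990374) fell from 33.1 ± 0.405 to 2.26 ± 0.382 (-3.39 ± 0.19), while Mxd4, a Max partner that opposes Myc, rose by 0.93 ± 0.12. The de novo DNA methyltransferase Dnmt3a fell from 143 ± 0.481 to 22.7 ± 5.17 (-2.62 ± 0.18), and its cofactor Dnmt3l from 237 ± 4.36 to 75.2 ± 0.0878. The microRNA host transcripts Mirg and Mir17hg rose by 2.33 ± 0.09 and 2.25 ± 0.10; Mir17hg went from 16.1 ± 0.0415 to 80.7 ± 6.5. Among epithelial genes the claudin Cldn7 rose by 1.87 and desmoplakin (Dsp) by 1.78, among trophoblast genes Tfap2c by 1.61 and Tead4 by 1.49, and among mesenchymal genes N-cadherin (Cdh2) rose by 1.79 while smooth muscle actin (Acta2) fell by 2.11. Core pluripotency factors outside the naming rule, picked after their values were seen, went different ways. Nanog was at 208 ± 1.18 FPKM in WT and 380 ± 10.2 in Dgcr8 KO (0.87), Sox2 at 137 ± 2.88 and 281 ± 19.4 (1.03), and Pou5f1 at 1036 ± 11.5 and 742 ± 80.8 (-0.49).

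Of the 27 gene lists tested, 6 moved against the other genes by camera in Dgcr8 KO, 5 upwards and 1 downwards. All 10 endoderm markers tested, of 16 in the list, fell, also when adjusted over the list alone, with a median of -2.46 (adjusted p = 1.39e-06, and adjusted p = 0.121 with an estimated correlation). Gata6, a primitive endoderm transcription factor, fell from 10.3 ± 0.129 to 0.155 ± 0.0403 FPKM. Among the markers too low to test Cxcr4 alone had a higher mean in Dgcr8 KO, at 0.722 FPKM against 0.307 in WT. Of the ESCC microRNA targets 14 of 16 rose (14 adjusted over the list alone), with a median of 1.04 (adjusted p = 1.70e-05, and 0.121 as adjusted p with an estimated correlation). Among them the Nodal inhibitor Lefty1 rose from 9.65 ± 0.543 to 97.1 ± 19.5 and the interferon regulatory factor Irf2 from 0.325 ± 0.272 to 9.39 ± 0.522. Dkk1, a member of the list too low to test, had a lower mean in Dgcr8 KO (0.0356 FPKM) than in WT (2.31). Mbnl1 and Mbnl2 are on this list because the study names them, so they are not independent evidence of its direction. The G1/S inhibitors had 13 of 15 members higher and 1 lower (13 and 1 adjusted over the list alone; median 0.91, adjusted p = 6.98e-04, and adjusted p = 0.129 with an estimated correlation). The Hippo kinase Lats2 rose from 1.69 ± 0.0609 to 9.73 ± 0.494, whereas the cyclin-dependent kinase inhibitor Cdkn1c fell by 2.30. Of the interferon-stimulated genes, 22 in the list, 8 of the 10 tested rose (8 adjusted over the list alone; median 1.36, adjusted p = 5.55e-04, and adjusted p = 0.245 with an estimated correlation). Of the 12 too low to test Ifit2 alone had a lower mean in Dgcr8 KO (0.119 FPKM) than in WT. MicroRNA host transcripts had 11 higher and 4 lower of 15 (the same adjusted over the list alone; median 0.55, adjusted p = 0.0297, and adjusted p = 0.322 with an estimated correlation). The Hippo pathway had 11 higher and 2 lower of 17 (11 and 3 adjusted over the list alone; median 0.49, adjusted p = 0.0409, and adjusted p = 0.261 with an estimated correlation), a call lost without WT replicate 1 (0.0508) or Dgcr8 KO replicate 2 (0.0543) and under median-of-ratios scaling (0.0507). With estimated correlations camera called 0 lists (5 did at an unadjusted p under 0.05), and fry found 20 lists moving one way and 25 moving in either direction.

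Camera did not call the other lists in Dgcr8 KO, although most had members that changed in both directions. Without Dgcr8 KO replicate 1 it called glycolysis (lower, median -0.36, adjusted p = 0.041) and mitochondrially encoded genes (higher, median 0.47, adjusted p = 0.041). The following counts give members higher and lower over all genes tested, with the counts adjusted over the list alone where these differ. Of 26 pluripotency genes 7 were higher and 13 lower (7 and 14 adjusted over the list alone; median -0.29), of 12 DNA methylation enzymes 3 and 9 (median -0.54), and of 15 germline genes 3 and 10 (median -0.48). Of 24 genes of Nodal, TGF-beta and BMP signalling 11 were higher and 4 lower (median 0.30), of 16 epithelial markers 10 and 4 (10 and 5 adjusted over the list alone; median 0.46), and of 9 mesenchymal markers 6 and 2 (median 0.80). The neuroectoderm markers had 5 higher and 1 lower of 9 (median 0.53), the trophoblast markers 4 and 4 of 9 (median 0.11), and the 4 mesoderm markers tested, too few for the list test, 2 and 1. Of 44 splicing regulators 11 were higher and 18 lower (median -0.09, mean 0.01). The microRNA pathway had 9 higher and 4 lower of 15 (median 0.31), the Myc family and partners 8 and 3 of 12 (median 0.44), and the G1/S cyclins and E2F factors 6 and 8 of 18 (median -0.16). Glycolysis genes had 4 higher and 9 lower of 21 (median -0.23), reference genes 2 and 8 of 14 (3 and 8 adjusted over the list alone; median -0.24), and actin cytoskeleton and adhesion genes 9 and 7 of 27 (10 and 7 adjusted over the list alone; median 0.07, and -0.06 without Dgcr8 KO replicate 1). The direction of the mitochondrially encoded genes rests on single libraries. They had 3 of 13 higher (1 adjusted over the list alone) and a median of 0.11, which was -0.22 without Dgcr8 KO replicate 2 and -0.09 without WT replicate 1. There were 3 higher and 2 lower of 8 mouse embryonic fibroblast markers (3 and 3 adjusted over the list alone; median 0.11, and -0.05 without Dgcr8 KO replicate 1). The median and the mean differed in sign for primed epiblast markers (5 higher and 5 lower of 12, 5 and 7 adjusted over the list alone; -0.36 and 0.22), let-7 targets (9 and 5 of 16, 10 and 6 adjusted over the list alone; 0.31 and -0.03) and p53 targets (6 and 6 of 18; -0.09 and 0.09). None of 18 two-cell-like markers passed limma's test in Dgcr8 KO, and 0 passed at an unadjusted p under 0.05 (median 0.29). Single libraries moved further medians: without Dgcr8 KO replicate 1 the cyclins were at -0.07 and the primed epiblast markers at -0.24, and without replicate 2 the cyclins were at -0.24, the p53 targets at -0.03, the fibroblast markers at 0.30 and the actin genes at 0.16. Without WT replicate 1 the trophoblast markers were at 0.07 and the p53 targets at -0.05, and without WT replicate 2 the mitochondrially encoded genes were at 0.27. Under quantile normalization pluripotency genes had 9 higher and 9 lower (median -0.02), splicing regulators 17 higher and 7 lower, reference genes 4 and 4, cyclins 6 and 6, actin genes 14 and 6 (median 0.27) and fibroblast markers 2 and 3, and the medians of the DNA methylation enzymes, the two-cell-like markers and the mitochondrially encoded genes were -0.35, 0.06 and 0.26. It turned the medians of the splicing regulators (0.14), glycolysis (0.07), reference genes (0.04), cyclins (0.01), trophoblast (-0.02) and fibroblast markers (-0.06).

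**Figure D2:**
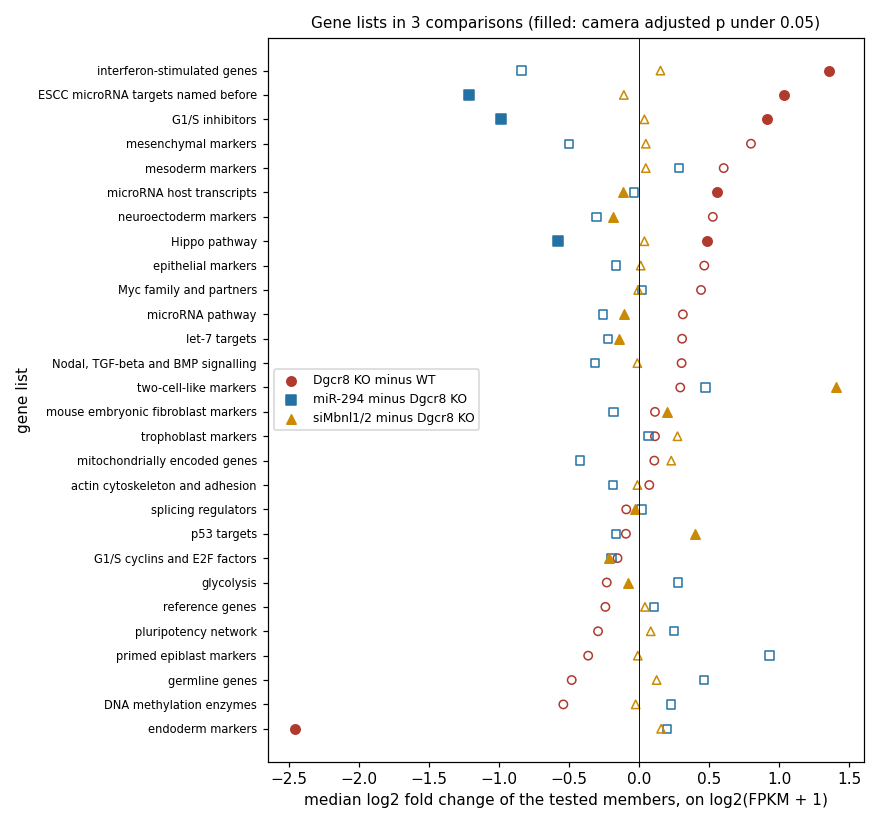
Median log2 fold change of the tested members of each gene list in the 3 comparisons with Dgcr8 KO or WT as reference; filled symbols passed camera with the preset correlation. Endoderm markers lie at -2.46 in Dgcr8 KO, ESCC targets at 1.04 in Dgcr8 KO and -1.21 after miR-294, and two-cell-like markers at 1.41 after siMbnl1/2.

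Putting miR-294 back into Dgcr8 KO cells raised Lin28a and Myc and lowered Msln, Irf2 and Cdkn1a. Lin28a rose from 5.13 ± 0.558 to 95.2 ± 1.59 FPKM (3.98 ± 0.11, adjusted p = 4.86e-06) and Myc from 2.26 ± 0.382 to 27.4 ± 1.03 (3.12 ± 0.19, adjusted p = 4.57e-05), against 109 and 33.1 in WT. Calca, the calcitonin gene, rose from 2.44 ± 0.342 to 48.3 ± 0.539 (3.85), Spink1 by 3.55, and RP23-255F14.8, an entry named after a genomic clone, by 3.17. Msln fell from 71.2 ± 10.6 to 9.16 ± 0.0456 (-2.82 ± 0.11, adjusted p = 1.76e-05), and Irf2 from 9.39 ± 0.522 to 0.619 ± 0.00645 (-2.68 ± 0.15). The ubiquitin ligase Trim47 (-2.82), the metalloproteinase Mmp23 (-2.74) and the immunoproteasome subunit Psmb8 (-2.63) were the other largest decreases of the genes admitted. Cdkn1a, the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090979 to 29100722), was at 25.4 ± 0.713 in WT and 60.7 ± 5.16 in Dgcr8 KO and fell to 16.9 ± 1.17 (-1.78 ± 0.08, adjusted p = 3.02e-05).

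The comparison called 6671 genes, 2934 higher and 3737 lower, and 941 of them by at least 2-fold (280 higher, 661 lower). The excess of lower genes depends on the scaling, with 3422 higher and 3418 lower under median-of-ratios scaling and 3279 and 3124 under quantile normalization. In this comparison 3 lists moved against the other genes by camera, all downwards. All 16 ESCC microRNA targets tested fell, also when adjusted over the list alone, with a median of -1.21 (adjusted p = 1.13e-06, and adjusted p = 0.121 with an estimated correlation). Lefty1 fell from 97.1 ± 19.5 to 23.9 ± 1.51. Of the G1/S inhibitors 13 of 15 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.99, adjusted p = 1.19e-04, and adjusted p = 0.121 with an estimated correlation). The pocket protein Rbl2 fell from 8.96 ± 0.563 to 2.35 ± 0.0159, Lats2 fell from 9.73 ± 0.494 to 2.86 ± 0.171, and Cdkn1c rose by 1.09. Of 17 Hippo pathway genes 11 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.58, adjusted p = 0.0126, and adjusted p = 0.236 with an estimated correlation), and the transcription factor Tead4 fell by 1.15. With estimated correlations camera called 0 lists (3 did at an unadjusted p under 0.05), and fry found 19 lists moving one way and 25 in either direction.

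Among lists not called as a whole after miR-294, 6 of 10 interferon-stimulated genes fell and 2 rose (median -0.84, adjusted p = 0.115). Zbp1 fell from 16.6 ± 1.5 to 2.05 ± 0.174 and Oasl2 from 10.7 ± 0.976 to 1.21 ± 0.29. Endoderm markers had 4 higher and 2 lower of 10 with a median of 0.20, and Gata6 reached 0.759 ± 0.0253 against 10.3 ± 0.129 in WT. Of 26 pluripotency genes 14 rose and 7 fell (median 0.25, and 9 and 7 with a median of 0.03 under quantile normalization), the nuclear receptor Nr5a2 from 6.19 ± 0.0856 to 16.4 ± 0.237. Dnmt3l rose from 75.2 ± 0.0878 to 434 ± 1.86, against 237 ± 4.36 in WT, and Dnmt3a from 22.7 ± 5.17 to 54.6 ± 0.725, against 143 ± 0.481 in WT. The Wnt effector Lef1 rose from 0.546 ± 0.315 to 6.84 ± 0.153 while Cdh2, another primed epiblast marker, fell by 1.29. Of the germline homeobox genes Rhox5 rose by 2.01 and Rhox9 fell by 1.82, and of the neuroectoderm genes Ncam1 fell by 1.30 and Sox1 by 1.13. The host transcript Mir17hg, at 87.8 ± 6.97, did not pass the test against Dgcr8 KO (0.12 ± 0.10, adjusted p = 0.339), and the let-7 target Igf2bp3 fell by 0.97 to 7.37 ± 0.125, against 12.3 ± 0.338 in WT. Without Dgcr8 KO replicate 1 camera also called glycolysis (higher, median 0.34, adjusted p = 0.0101) and mitochondrially encoded genes (lower, median -0.70, adjusted p = 0.00881). Glycolysis was also called under median-of-ratios scaling (adjusted p = 0.0432). Quantile normalization added actin cytoskeleton and adhesion genes (lower, median -0.20, adjusted p = 0.00834) and splicing regulators (lower, adjusted p = 0.0391), whose median went from 0.02 to -0.19. Weighted libraries added two-cell-like markers (higher, adjusted p = 0.0304).

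Genes whose longest 3' UTR holds a match to the miR-294 seed were lower after miR-294 than genes without one. The median change was -0.24 for 2004 genes with the heptamer and -0.03 for 9493 genes without, a difference of -0.20, and 69.9% and 53% of them had a negative change. UTR length alone accounted for -0.09, which leaves -0.11 beyond length (permutation p = 1e-05, the smallest the permutations can give). None of 20 shuffled heptamers gave as low a difference; theirs ran from -0.16 to 0.01. The median was -0.23 for 1623 genes with 1 match and -0.27 for 381 genes with more. In Dgcr8 KO minus WT the same genes were higher by 0.12 beyond UTR length (permutation p = 1e-05), and after siMbnl1/2 they differed by 0.00317 (permutation p = 0.494). A match was present in 14 of 16 ESCC targets and 6 of 15 G1/S inhibitors, with 2 in Cdkn1a, 2 in Lats2, 1 in Mbnl2 and 0 in the longest annotated UTR of Mbnl1. Genes are not independent replicates, and 89.9% of those tested had an annotated 3' UTR.

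**Figure D3:**
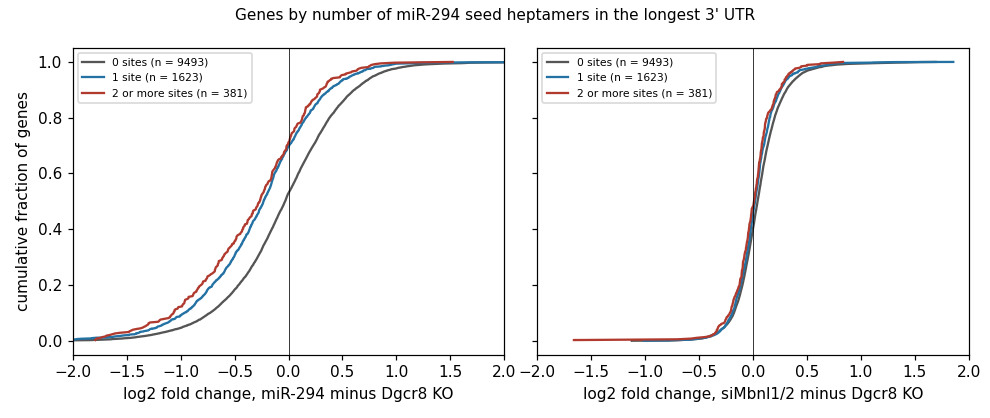
Cumulative fraction of genes against log2 fold change after miR-294 and after siMbnl1/2, for genes with 0 (9493), 1 (1623) and 2 or more (381) seed heptamers in the longest 3' UTR. After miR-294 the curves of genes with a heptamer lie to the left, with medians of -0.23 and -0.27 against -0.03, and after siMbnl1/2 the curves nearly overlap.

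Transfection of siMbnl1/2 into Dgcr8 KO cells raised Cdkn1a, Mdm2, Tagln and Tmem92 and lowered Serpinf1 along with Mbnl2. Cdkn1a rose from 60.7 ± 5.16 to 109 ± 4.76 FPKM (0.84 ± 0.08, adjusted p = 0.0124), and Mdm2, the ubiquitin ligase of p53 and itself a p53 target, from 50.9 ± 0.905 to 74.7 ± 6.59 (0.54 ± 0.08, adjusted p = 0.0378). The actin-binding protein transgelin (Tagln) rose from 14.8 ± 1.44 to 43.5 ± 4.53 (1.49 ± 0.13, adjusted p = 0.0124), and the myosin light chain Myl9 from 5.31 ± 1.43 to 11.4 ± 0.192. Tmem92, a two-cell-like marker, showed the largest increase of the genes admitted, from 2.36 ± 0.0129 to 11.6 ± 4.63 (1.86 ± 0.22, adjusted p = 0.0185). Serpinf1, a secreted serpin, fell from 28.5 ± 2.85 to 12.6 ± 1.27 (-1.12 ± 0.10, adjusted p = 0.0124), against 11.1 ± 0.784 in WT. Of 14 alternative settings, 9 lost the call of Mdm2, 7 that of Myl9, 5 that of Tmem92, 3 that of Cdkn1a, 2 that of Tagln and 1 that of Serpinf1.

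After siMbnl1/2 142 genes passed, where 6671 had after miR-294, 111 higher and 31 lower, and 27 changed by at least 2-fold (23 higher, 4 lower). The carboxypeptidase Cpz (1.55), Kdm4dl (1.41) and Dhtkd1 (1.34), a mitochondrial enzyme of lysine breakdown, rose as well, and the maternal factor Dppa3 rose by 0.84. Decreases other than Mbnl2 and Serpinf1 were Mid1ip1 (-1.01), a regulator of lipid synthesis, sulfiredoxin (Srxn1, -0.76), the alanine transaminase Gpt2 (-0.75), the activin subunit Inhbb (-0.73) and cyclin D2 (Ccnd2, -0.54). Both groups of this comparison are the ones with the wider spread, and the pooled variance draws on the quieter WT and miR-294 libraries. With libraries weighted by the spread of their group 8 genes passed, all among the 142, and Serpinf1 was the only named gene among them. A fit to the 4 libraries of the comparison alone called 4, and Serpinf1 was not among them (adjusted p = 0.0972). The count was 81 without Dgcr8 KO replicate 1, 15 without Dgcr8 KO replicate 2 and 650 without siMbnl1/2 replicate 2, and without Dgcr8 KO replicate 2 Serpinf1 was again the only named gene that still passed. The share of higher genes among those called, 78.2%, was 56.4% after median-of-ratios scaling and 57.1% after quantile normalization. It turned to 3 higher and 12 lower without Dgcr8 KO replicate 2 and to 1 and 3 with the libraries of the comparison alone, and was 4 and 4 with weighted libraries.

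Of the lists, 10 moved after siMbnl1/2 by camera with the preset correlation, 3 upwards and 7 downwards, with few single members past the threshold. Two-cell-like markers, which include the Zscan4 genes of the zygotic genome activation stage, had a median of 1.41 with 1 of 18 members past the threshold and all 18 higher when adjusted over the list alone (adjusted p = 1.17e-09, and adjusted p = 0.396 with an estimated correlation). Their mean log2 level was 3.8 in siMbnl1/2 replicate 1 and 2.53 in replicate 2, against 1.80 and 1.85 in Dgcr8 KO, and the median was 0.72 without replicate 1 (9 called) and 2.11 without replicate 2 (18 called). The call of Tmem92 was lost without either Dgcr8 KO library and with weighted libraries. The p53 targets had 2 of 18 members higher (9 without siMbnl1/2 replicate 2, 1 without siMbnl1/2 replicate 1, and both calls lost without Dgcr8 KO replicate 2 or with weighted libraries), 12 higher and 1 lower adjusted over the list alone, and a median of 0.40 (adjusted p = 6.21e-07, and adjusted p = 0.289 with an estimated correlation). G1/S cyclins and E2F factors were lower with a median of -0.22 and 1 of 18 members called (3 adjusted over the list alone; adjusted p = 1.42e-07, and adjusted p = 0.155 with an estimated correlation). For let-7 targets the median was -0.14 (1 higher and 6 lower of 16 adjusted over the list alone; adjusted p = 8.13e-04, and adjusted p = 0.155 with an estimated correlation). For the microRNA pathway it was -0.11 (2 of 15 lower adjusted over the list alone; adjusted p = 0.00128, and adjusted p = 0.155 with an estimated correlation). The medians shrank to -0.05 and -0.06 without siMbnl1/2 replicate 1 and to -0.09 and -0.07 without Dgcr8 KO replicate 1. limma called 0 members of those 2 lists, with 1 higher and 7 lower and with 2 lower at an unadjusted p under 0.05. Fibroblast markers were higher (median 0.20, adjusted p = 0.0474, and adjusted p = 0.54 with an estimated correlation) with Tagln, which WT cells also express (30.6 ± 5.01 FPKM), as the called member of 8, and 2 higher adjusted over the list alone.

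The remaining calls after siMbnl1/2 were lost when single libraries were left out. Glycolysis (median -0.08, adjusted p = 0.0101, and adjusted p = 0.593 with an estimated correlation) was not called without Dgcr8 KO replicate 1 (adjusted p = 0.30, where the median was 0.01) or siMbnl1/2 replicate 1 (0.14). MicroRNA host transcripts (median -0.12, adjusted p = 0.0146, and adjusted p = 0.338 with an estimated correlation) were not called without Dgcr8 KO replicate 1 (0.104) or siMbnl1/2 replicate 2 (0.0793). Splicing regulators (median -0.03, adjusted p = 0.0474, and adjusted p = 0.582 with an estimated correlation) lost the call without Dgcr8 KO replicate 2 (0.482) or siMbnl1/2 replicate 2 (0.764), where the median was 0.07. Neuroectoderm markers (median -0.19, adjusted p = 0.0494, and adjusted p = 0.338 with an estimated correlation) lost it without the same libraries (0.191 and 0.413) and in most other settings, and kept it in 2 of 9. The fibroblast markers lost it without either Dgcr8 KO library (0.0856 and 0.101) or siMbnl1/2 replicate 2 (0.378) and with a replicate block (0.0508). Camera also called mitochondrially encoded genes without Dgcr8 KO replicate 2 (higher, median 0.40, adjusted p = 3.09e-05) and trophoblast markers without siMbnl1/2 replicate 1 (higher, median 0.41, adjusted p = 0.00897). limma called 0 genes of the glycolysis, host transcript and neuroectoderm lists. At an unadjusted p under 0.05 it had 1 higher and 4 lower of 21 glycolysis genes. There were 1 higher and 2 lower of 15 host transcripts, and 0 higher and 3 lower of 9 neuroectoderm markers. Adjusted over the list alone, 3 neuroectoderm markers were lower. Of the 44 splicing regulators Mbnl2 alone was called (also adjusted over the list alone), and at an unadjusted p under 0.05 limma had 2 higher and 4 lower. ESCC targets, with 1 higher (Cdkn1a) and 1 lower (Mbnl2) of 16, did not move as a list (median -0.11, adjusted p = 0.101), and neither did the interferon-stimulated genes (median 0.15, adjusted p = 0.214). With 1 library left out the medians in this paragraph ran from -0.15 to 0.01 for glycolysis, -0.34 to -0.09 for neuroectoderm markers, 0.08 to 0.32 for fibroblast markers, -0.21 to -0.01 for ESCC targets and 0.03 to 0.26 for interferon-stimulated genes. For the host transcripts the median was -0.07 without Dgcr8 KO replicate 1 and for the splicing regulators -0.11 without siMbnl1/2 replicate 1. With correlations estimated, camera called 0 lists (4 did at an unadjusted p under 0.05), and fry found 9 lists moving one way and 19 in either direction.

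Between the transfections, the 3 largest differences in each direction among the genes admitted lay in genes that miR-294 had changed. Lin28a was at 3.16 ± 0.582 FPKM with siMbnl1/2 and 95.2 ± 1.59 with miR-294 (-4.54 ± 0.11, adjusted p = 2.00e-06), Calca was lower by 4.12 and Spink1 by 3.39. Zbp1 was higher with siMbnl1/2, at 23.0 ± 1.25 against 2.05 ± 0.174 (2.98), as were Psmb8 (2.90) and Msln (2.84). Cdkn1a differed by 2.62 ± 0.08 (adjusted p = 6.61e-06). Mbnl2 did not differ by more than the spread (-0.11 ± 0.12, adjusted p = 0.467), and Mbnl1 was higher with the siRNAs by 0.37 ± 0.10 (adjusted p = 0.0165), a call lost without either miR-294 library and under both scalings, where the adjusted p reached 0.459. In total 6902 genes differed, 4217 higher and 2685 lower with siMbnl1/2. The median of all genes lay at 0.10, and scaling by median of ratios or by quantiles moved it to 0.00 and -0.02 and the split to 3477 higher and 3461 lower or 3131 and 3382. By camera 5 lists differed. ESCC targets were higher with siMbnl1/2 by a median of 1.07 (15 of 16 members, also adjusted over the list alone; adjusted p = 1.08e-04, and adjusted p = 0.144 with an estimated correlation). G1/S inhibitors were higher by 1.05 (14 higher and 1 lower of 15; adjusted p = 1.11e-04, and adjusted p = 0.144 with an estimated correlation). Hippo pathway genes (median 0.56, adjusted p = 0.00543, and adjusted p = 0.203 with an estimated correlation) and p53 targets (median 0.52, adjusted p = 0.0184, and adjusted p = 0.582 with an estimated correlation) were also higher. Glycolysis genes were lower (median -0.33, adjusted p = 0.00543, and adjusted p = 0.743 with an estimated correlation).

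Across genes, the changes after miR-294 ran along the difference between WT and Dgcr8 KO, while those after siMbnl1/2 had a covariance with it that lay between the values of 2 simulations of shared controls. Of the 3789 genes higher in Dgcr8 KO, 2825 (74.6%) fell after miR-294 and 59 rose further; of the 3852 lower genes, 2439 (63.3%) rose and 74 fell further. After siMbnl1/2, 13 of the higher genes fell and 35 rose, and 44 of the lower genes rose and 13 fell. The log2 changes of miR-294 minus Dgcr8 KO and WT minus Dgcr8 KO correlated across 12786 genes at a Pearson r of 0.748 (Spearman 0.794). Simulated unchanged groups that share the same controls gave an r of 0.492 with a common spread and 0.614 with each group's own spread. The covariance was 0.337, against 0.0321 and 0.0441 in these simulations. Independent calls would give 884 genes higher in both and 1107 lower in both, where 2439 and 2825 were seen. For siMbnl1/2 and WT the r was 0.177 (Spearman 0.105), where the simulations gave 0.502 and 0.561. Changes confined to a single comparison lower r and not the covariance. The covariance was 0.0427, against 0.0330 in the simulation with a common spread and 0.0451 in that with each group's own spread. With a different control library in each comparison the r was 0.0112 and -0.0192. The changes after miR-294 and siMbnl1/2 correlated at 0.231 (Spearman 0.139), where the simulations gave 0.499 and 0.540. Their covariance was 0.0458, against 0.0326 and 0.0447 in the simulations, and their r was -0.0262 and 0.0430 with a different control library in each. Both treatments raised 38 genes and lowered 13, where independent calls would give 25.5 and 9.06. Another 10 were higher with miR-294 and lower with siMbnl1/2 (7.11 if independent), and 34 the reverse (32.4 if independent). The independent values leave out the shared Dgcr8 KO libraries, which alone favour calls in the same direction, so the excess over them is no measure of a shared effect, and genes are not independent replicates.

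**Figure D4:**
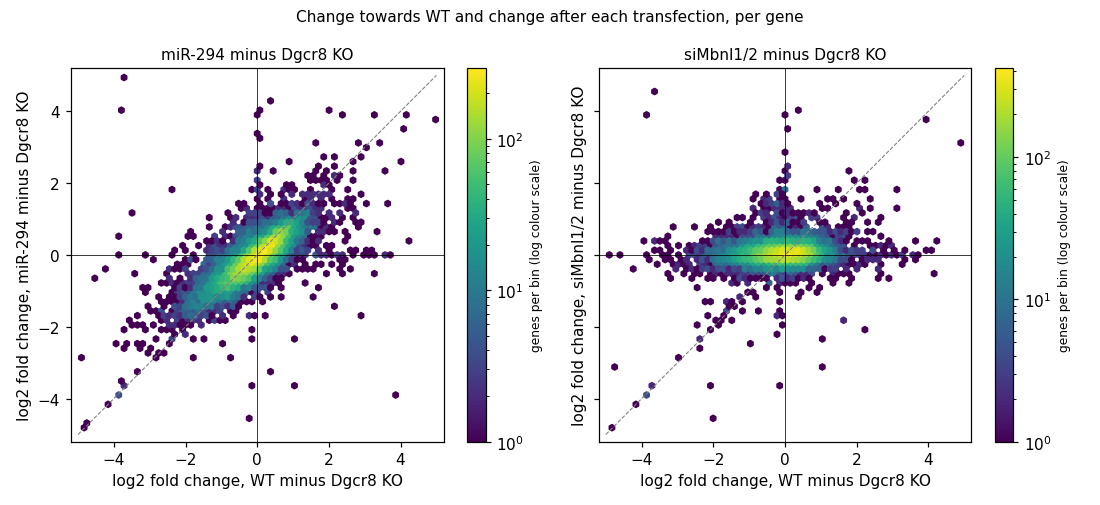
Log2 fold change after miR-294 (left) and after siMbnl1/2 (right) against the difference between WT and Dgcr8 KO for 12786 genes, as counts of genes per hexagon on a log colour scale; the dashed line marks equal change. Genes follow the dashed line on the left (r = 0.748) and stay near 0 on the right (r = 0.177). Simulated unchanged groups with shared controls gave an r of 0.492 and 0.614 for the left pair and 0.502 and 0.561 for the right.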

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

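The tests on the two-cell-like markers, on the interferon-stimulated genes and on the scaling of the p53 targets were chosen after the results were seen; the test of the p53 targets without a seed match was set before its result was seen.

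Cdkn1a, which encodes the cell cycle inhibitor p21, moved in opposite directions in the same cells. It rose from 60.7 ± 5.16 FPKM (n = 2) to 109 ± 4.76 after siMbnl1/2 and fell to 16.9 ± 1.17 after miR-294, a difference of 2.62 ± 0.08 on the log2 scale (limma, adjusted p = 6.61e-06) that holds in every library of the 2 groups. Of 95 genes called after both transfections 44 moved in opposite directions, 34 higher with siMbnl1/2 and 10 lower, where independent calls would give 32.4 and 7.11. Those values leave out the shared Dgcr8 KO libraries, which favour calls in the same direction. Of the genes that went the other way, higher with miR-294 and lower with siMbnl1/2, 4 were picked after their values were seen. Phgdh, the first enzyme of serine synthesis, differed by -1.61 ± 0.11, and Psat1, a later enzyme of that pathway, by -1.32 ± 0.05. Nars, an aminoacyl-tRNA synthetase, differed by -1.39 ± 0.05, and the transcription factor Atf5 by -1.10 ± 0.08. For all of these genes the change after siMbnl1/2 is the smaller part, and its call belongs to the 142 that depend on how the spread is pooled; Cdkn1a is not called when libraries are weighted by the spread of their group (adjusted p = 0.0537), without Dgcr8 KO replicate 2 (adjusted p = 0.0658 for Cdkn1a, siMbnl1/2 minus Dgcr8 KO) or with the libraries of the comparison alone (adjusted p = 0.0972).

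Two-cell-like markers had a median change of 1.41 over 18 genes after siMbnl1/2, with 1 of the 18 past the threshold over all genes (0 to 18 over the alternatives, where the median ran from 0.72 to 2.11); camera called the list with the preset correlation and not with an estimated one (adjusted p = 0.396). A single library was argued against as the whole source, since the lowest median with any 1 library left out was 0.72, without siMbnl1/2 replicate 1, and the mean log2 level of 2.53 in replicate 2 lay above 1.80 and 1.85 in Dgcr8 KO. Reads shared between near-identical copies stay open: the 3 members without such copies (Tmem92, Arg2 and Zfp352) had a median of 1.35, but only Tmem92 passed the test. A response to any transfected small RNA also stays open, because the list's median was 0.47 after miR-294, 33.6% of that after siMbnl1/2, and Tmem92, Arg2 and Zfp352 passed the test there. No untreated or scrambled siRNA control is among these samples, and a share of cells entering a two-cell-like state may differ between cultures of 1 condition.

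Of the interferon-stimulated genes 8 of the 10 tested, of 22 in the list, were called higher in Dgcr8 KO, with a median of 1.36 (camera adjusted p = 0.245 with an estimated correlation) and mean log2 levels of 4.10 and 3.95 in its libraries against 2.55 and 2.52 in WT. RNA from feeder fibroblasts was argued against: the fibroblast collagens Col1a1, Col1a2 and Col3a1 stayed at 0.173 FPKM or less in Dgcr8 KO and were not higher than in WT, where they were at 0.403, 0.373 and 0.177. A lasting difference between the cell lines that does not depend on microRNAs stays open. After miR-294 6 of the 10 genes fell and 2 rose, with a median change of -0.84. Camera did not call the list there (adjusted p = 0.115, and adjusted p = 0.615 with an estimated correlation). An added microRNA can lower genes whatever had raised them, so this change cannot decide the question. As a hypothesis, part of the difference between Dgcr8 KO and WT may depend on microRNAs. Only the change after miR-294 bears on it here, and by what route was not tested. Of the 10 genes 4 carry the seed heptamer, a larger share than the 2004 of 11497 among all tested genes with an annotated 3' UTR. This share was not tested, and UTR length was not taken into account. In other lists not called after miR-294 it was 6 of 12 (Myc family and partners), 7 of 18 (p53 targets) and 1 of 16 (epithelial markers). Oasl2 has a match and Zbp1 has none. The double-stranded precursors left without Dgcr8 were not measured.

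The p53 targets had a median change of 0.40 over 18 genes after siMbnl1/2, with 2 of the 18 past the threshold over all genes (0 to 9 over the alternatives); camera called the list with the preset correlation and not with an estimated one (adjusted p = 0.289). Their mean log2 levels were 5.29 and 5.14 against 4.91 and 4.88 in Dgcr8 KO. Scaling between libraries was argued against, since the median was 0.34 under median-of-ratios scaling and 0.38 under quantile normalization. A p53 response to any transfected small RNA cannot be told apart from an effect of the siRNAs on their targets, of which Mbnl2 passed the test and Mbnl1 did not (adjusted p = 0.158). The 11 targets without a seed heptamer had a median of -0.035 after miR-294, where 0.38 was seen after siMbnl1/2. By the rule set before the result, a median of 0 or less would count against a response to any small RNA, and this median met it. A further condition, that the upper quartile be 0 or less, was not part of that rule and was not met. The quartiles ran from -0.52 to 0.09, and miR-294 has its own effects and is no neutral control, so no conclusion is drawn.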

How the results depend on the processing

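Weighting libraries by the spread of their group, and giving each group its own spread in the simulated controls, were chosen after the data were seen; the other alternatives were planned. The counts of Dgcr8 KO minus WT, miR-294 minus Dgcr8 KO and siMbnl1/2 minus miR-294 stayed within 1.5 times under every alternative except the 2-fold minimum, which gave 1565, 941 and 1109; with 1 library left out they ran from 5770 to 6785, 4579 to 5729 and 4780 to 7035. The count after siMbnl1/2, 142 as reported, was 61 without a filter, 27 with the 2-fold minimum, 8 with weighted libraries, 4 from the libraries of the comparison alone and 15 to 650 with 1 library left out. The cause was not tested beyond a simulation with 200 changed genes. With the spreads of these groups 10.9% of its calls in this comparison were false, against 5.70% with equal spreads and 5.67% with weighted libraries. Weighting took its mean number of calls from 173 to 152, whereas the calls in these data went from 142 to 8. The simulated data differ from these in that respect, so 10.9% is no error rate of the 142. The number of genes called after siMbnl1/2 is uncertain. Of 222 checks of called named genes in this comparison 148 kept their call and 74 kept their direction without passing the threshold; in Dgcr8 KO minus WT all but 2 of 426 and in miR-294 minus Dgcr8 KO all 388 kept both. Between the transfections, 3 genes that were not called changed sign: the change of Dgcr8, siMbnl1/2 minus miR-294, was 0.03 as reported, -0.068 under median-of-ratios scaling and -0.22 under quantile normalization, and it ran from -0.0841 to 0.15 with 1 library left out, that of Mbnl2 from -0.28 to 0.051 and that of Mbnl3 from -0.14 to 0.025. The cause was not tested.

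No list was called by camera with an estimated correlation (0, 0 and 0 in the comparisons with Dgcr8 KO, and 5, 3 and 4 at an unadjusted p under 0.05). After miR-294, 5 lists were called under quantile normalization and 3 to 5 with 1 library left out, and after siMbnl1/2 6 to 10. The correlation of miR-294 with WT was 0.707 with a pseudocount of 0.1, 0.578 and 0.606 with 1 control library in each comparison and 0.716 to 0.771 with 1 library left out. That of siMbnl1/2 with WT was 0.0112 and -0.0192 with separate controls and 0.0966 to 0.291 with 1 library left out, and that of miR-294 with siMbnl1/2 -0.0262 and 0.0430, and 0.130 to 0.372. By construction separate controls remove the part of a correlation that shared controls add. The seed difference ran from -0.32 to -0.19 over 9 alternatives, all past the threshold.

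Replicate numbers as a block gave 7147 genes for Dgcr8 KO minus WT, 6082 for miR-294 minus Dgcr8 KO, 33 for siMbnl1/2 minus Dgcr8 KO and 6306 for siMbnl1/2 minus miR-294, and 6, 3 and 8 lists for those with Dgcr8 KO. The labels do not say whether the numbers pair the samples. Deviations of replicate 1 from its group mean correlated across genes at between -0.0495 and 0.191 over the pairs of groups, highest for WT with Dgcr8 KO. With 2 libraries per group these correlations cannot show whether libraries of the same number shared a day. Depth is unknown, so it cannot be said which of the genes that did not pass were too low to test. With 2 libraries per group a change of 0.5 on the log2 scale was recovered in 43.1% of simulated cases after siMbnl1/2, so smaller changes were mostly not detectable here.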

Other observations

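The genes in the next paragraph were picked after their values were seen; the tests of the ATF4 targets and of the antigen processing genes were set before their results were seen.

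Some transcripts were higher after both transfections than in mock-transfected Dgcr8 KO cells. Both comparisons share those 2 mock libraries, so low values in them alone would give the same picture. Gm26917 was at 46.9 ± 8.37 FPKM (n = 2) in mock-transfected Dgcr8 KO cells, 105 ± 0.507 with miR-294 and 106 ± 3.85 with siMbnl1/2, and Gm42418 at 262 ± 40.8, 415 ± 27.3 and 440 ± 31.2. Both lie in a genomic region that matches ribosomal RNA. Lars2, a mitochondrial leucyl-tRNA synthetase gene, went from 27.4 ± 2.68 to 62.0 ± 7.35 and 46.8 ± 2.29. All of these were lower in Dgcr8 KO than in WT, where Gm26917 was at 69.9 ± 5.16, Gm42418 at 391 ± 7.40 and Lars2 at 42.2 ± 0.717. The metabolic gene Dhtkd1 was at 10.8 ± 2.16 in Dgcr8 KO, 23.7 ± 0.55 with miR-294 and 29.1 ± 8.28 with siMbnl1/2, and Dppa3 at 5.42 ± 0.00303, 8.90 ± 0.422 and 10.6 ± 1.39. After siMbnl1/2 the call of Dhtkd1 was lost in 6 of 14 alternative settings and that of Dppa3 in 4. The predicted gene Gm10351 was at 27.9 ± 10.8 in Dgcr8 KO and is listed at 0 in all libraries of the other groups, the transfected Dgcr8 KO cells included.

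Phgdh, Psat1, Nars and Atf5 were lower after siMbnl1/2 and are known targets of ATF4, the transcription factor of the amino acid and stress response, so a lower ATF4 response is a candidate explanation. A list of 25 other ATF4 targets was written before their values were looked at, and 24 were tested. Their median change after siMbnl1/2 was -0.19, 21 of 24 were negative, and camera placed them below the other genes (p = 1.18e-07, and p = 0.155 with an estimated correlation). limma called 0 of them over all genes, with 2 higher and 11 lower at an unadjusted p under 0.05 and 2 higher and 5 lower adjusted over the list alone. The 2 that were higher were Ddit4 and Cth (0.30 each), and asparagine synthetase (Asns) stayed at 139 ± 9.51 (-0.04 ± 0.06, limma adjusted p = 0.793). After miR-294 19 of the 24 rose (19 adjusted over the list alone), with a median of 0.61 (camera p = 3.28e-09, and p = 0.122 with an estimated correlation). The glutathione-degrading enzyme Chac1 went from 7.96 ± 0.836 to 27.9 ± 0.349 and Asns from 143 ± 0.134 to 231 ± 5.46. In Dgcr8 KO 16 of the 24 were lower than in WT and 2 higher, with a median of -0.40. The prediction held by its rule with all libraries, but this list was not tested with single libraries left out. The libraries of some targets overlapped: Pycr1 was at 36.2 and 25.8 FPKM in Dgcr8 KO and 19.5 and 30.4 with siMbnl1/2. Those of others did not, such as Gars at 200 and 194 against 158 and 164. ATF4 activity was not measured, and amino acid supply to cells growing at different rates may give the same picture.

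Psmb8 and Erap1, which process peptides for MHC class I, were among the genes higher in Dgcr8 KO; Erap1 was at 0.531 ± 0.0323 in WT, 11 ± 1.05 in Dgcr8 KO and 1.09 ± 0.12 with miR-294. The hypothesis was that antigen processing genes change as a group. The list of 14 other genes tested also counts the transcription factor Irf1 as a member, which changed by 2.64 in Dgcr8 KO and by -1.43 after miR-294. Of the 14, 9 were higher and 1 lower in Dgcr8 KO (11 and 1 adjusted over the list alone), with a median of 0.54 (camera p = 9.25e-04, and p = 0.102 with an estimated correlation). After miR-294 11 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.69); the peptide transporter Tap1 went from 4.18 ± 0.798 to 1.25 ± 0.063, against 2.03 ± 0.0577 in WT. Antigen processing genes respond to interferon and Irf1 and overlap in regulation with the interferon-stimulated genes, so they may share a source with them and are not separate evidence.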
